A study of Arabidopsis thaliana with 12 samples.

How the data were processed

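RNA was sequenced from whole Arabidopsis thaliana seedlings of 4 genotypes at 14 days: wild type and the mutants pkl, clf and lhp1. The titles give 3 libraries per genotype, 12 in all, and each sample was placed in its group by its title. Nothing in the labels says whether the libraries of a group came from separate growth batches, so any spread between samples behind the p-values may be technical. Per the labels' protocols, plants grew on half-strength Murashige and Skoog medium at 22 °C with 16 h light and 8 h dark, and 1 µg of total RNA entered each library.

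Each of the 3 tables compares 1 mutant with wild type over the same 31788 loci, and per the file headers it is the gene-level output of Cuffdiff. The submitters' processing notes name TopHat, Cufflinks 2.1.1, Cuffdiff 2.1.1 and the genome build TAIR10; the version of TopHat, the strand setting and the library normalisation are not given in the sources used here. The authors deposited 1 FPKM value per group and locus (FPKM, fragments per kilobase of transcript, scaled to the mapped fragments); the tables do not state how many libraries entered each group's value and test. The deposited test statistic is a score whose sign follows the fold change. The deposited p-value and q-value come from the same comparison; the smallest p in the tables is 5e-05 and the smallest q is 0.000661. Wild-type FPKM differed between the tables at 0 loci, and equal p-values carried nearly equal q-values in all 3. The largest called p was 0.00845 in each, though the numbers of calls differed, which argues against an adjustment within each comparison alone. A q threshold then bounds false calls over the comparisons together, not within 1 mutant. Over how many tests the authors adjusted is not given in the sources used here. The deposited fold change column held text in place of numbers at some loci and was not used; log2 fold changes were computed here from the FPKM values. Values of single libraries were not used here.

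The design, the gene lists, the rule for naming genes and most alternatives were written before the data were examined. The design foresaw tables with group values only, and that branch was followed. A gene was called where the test status was OK and the deposited q was under 0.05, and "rose", "fell" and "changed" are used for such calls. Per-gene tests on replicates, such as a linear model on log2 values or a count model, could not be run, and values carry no standard deviation. Counts are of the 31554 loci with a gene name; 234 loci had none and 2059 held several genes, whose values cannot be assigned to 1 of them. Genes with near-identical copies, such as the RBCS and LHCB genes, VSP1 and VSP2 or the PDF1.2 family, are uncertain, since it is not stated how shared reads were divided, and so are overlapping and antisense genes. Of 33553 gene identifiers, 32806 matched the reference gene table (assembly TAIR10.1), which supplied symbols. Coordinates are those of the authors' merged loci on TAIR10.

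The depth behind the values is unknown, because FPKM keeps no counts. The spread the authors' test worked with was read back from the tables: the normal quantile of the p-value was a median of 1.74 times the absolute statistic in each table, which gives an implied standard error of the log2 fold change. In the pkl table its median was 0.144 for loci at 10 to 100 FPKM and 0.628 below 1 FPKM, so that small changes of weakly expressed genes were beyond these tables.

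The lists number 22. Members with a locus of their own were counted, and where the authors split a gene into several loci, as for PI, MYC2, RGL2 and KNAT6, the locus with the highest mean FPKM was taken; 22 list entries without one were left out of the counts, and 8 list symbols not in the reference table are given by its symbol or by the gene identifier. For each list and mutant, the called members were counted in each direction, also with the deposited p-values adjusted over the list alone (Benjamini-Hochberg). Over-representation of calls was tested with a one-sided Fisher's exact test against all tested single-gene nuclear loci, adjusted over the lists within each mutant and direction. The median log2((FPKM + 1)/(FPKM + 1)) was set against 10000 random lists of the same size matched on expression in 10 bins; its percentile describes these libraries. The lists cover the mutated genes, Polycomb factors, floral organ identity, flowering time, seed maturation, seed storage, meristem, leaf polarity, gibberellin, auxin, photosynthesis, cold and abscisic acid, salicylic acid and defence, jasmonate, glucosinolate, root, stomatal, anther, clock, cell cycle, heat shock and reference genes.

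Genes were named by a rule fixed at the same time: the 3 mutated genes; up to 4 members per list, called members with the largest absolute log2 fold change first; per mutant the 6 largest rises and 6 largest falls among called nuclear loci above 0 in both groups with at least 5 FPKM in the higher one; the 5 genes called higher and the 5 called lower in all 3 mutants with the largest smallest change; and the 5 called in opposite directions in 2 mutants with the largest difference.

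Overlaps were counted over loci tested in both tables and set beside the number for independent lists (n1 × n2 / N) and beside the mean of 100 simulations of unchanged mutants against the same wild type. Correlations used loci with at least 1 FPKM in 1 of the groups, on the log2(FPKM + 1) scale. The simulated noise took the implied standard errors as the root mean square over loci of like expression, the upper 5% left out. That pooling was chosen after the first result was seen: with each locus's own implied standard error the simulated covariance was 0.331 for pkl and clf, 0.329 for pkl and lhp1 and 0.353 for clf and lhp1, larger than the observed 0.0273, 0.0708 and 0.148. With the pooled noise it was 0.0176 in all 3 pairs. The own noise is too large for these data. The observed covariance divided by r measures the total spread of the fold changes. In each pair it was below the covariance simulated from own noise alone. The observed covariance exceeds that of the pooled noise, but the size of the pooled noise was not checked otherwise. The simulated overlaps use the pooled noise as well.

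The scripts were tested on simulated data over 19019 loci, made from the real levels and the pooled noise described above. Changes were planted at 200 loci with a mean of at least 1 FPKM. For pkl, 46% of loci changed 1.5-fold, 88% of those changed 2-fold and 100% of those changed 4-fold were called; for clf the shares were 42%, 88% and 98%, and for lhp1 42%, 90% and 94%. Unchanged loci made up 4.02%, 5.20% and 6.32% of the calls. The planted covariance shared by 2 mutants, 0.0310 for pkl, was recovered as 0.0318 after the simulated value was subtracted. The same pooled noise made the data and was subtracted, so the recovery checks the arithmetic and cannot show whether that noise is right. The share of unchanged calls rests on it too. These simulations test the procedures used here, not the authors' own test.

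The alternatives fixed with the design were a q threshold of 0.01, a 2-fold minimum, minimums of 1 and 5 FPKM, q-values recomputed within each table, centred fold changes, a pseudocount of 0.1 and Spearman's rho. Others, chosen after the data had been seen, concern unnamed and multi-gene loci, loci listed at 0 and the deposited statistic. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.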

Results

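Transcripts were measured by RNA-seq in whole 14-day-old Arabidopsis seedlings of wild type and of 3 mutants, with 3 libraries per genotype by their titles. PKL (PICKLE) is a CHD3-type chromatin remodeller, CLF (CURLY LEAF) is a Polycomb methyltransferase that places H3K27me3, and LHP1 (LIKE HETEROCHROMATIN PROTEIN 1) binds that mark. The series title ties PICKLE to the spreading of H3K27me3, so the comparisons ask which genes each mutant changes and how far the mutants change the same ones. Expression is given as the authors' FPKM, 1 value per group, so no value carries a replicate error and library depth is unknown. The group FPKM values sum to 961279 in wild type, 980745 in pkl and 992382 in clf, where 75606.5 came from 1 short locus without a gene name, and the sum of lhp1 was 94.8% of that of wild type; 17885 loci of wild type reach 1 FPKM.

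PKL and LHP1 were called lower in their own mutants, and CLF was lower in value but not called. PKL (AT2G25170) stood at 20.8 FPKM in wild type and 6.83 in pkl, with q = 0.000661 in the authors' deposited table, and at 21.5 in clf and 20.7 in lhp1. LHP1 (AT5G17690, also named TFL2) stood at 12.1 FPKM in wild type, was listed at 0 in lhp1 and was called lower there. CLF (AT2G23380) stood at 8.37 FPKM in wild type and 0.264 in clf, a log2 fold change of -4.99, but its q of 0.0520 in the authors' deposited table missed the threshold; adjusted over the list alone, 1 of the 3 mutated genes was lower in clf, 1 in pkl and 1 in lhp1. The loci lie on TAIR10 at chromosome 2, 10712606 to 10723989, chromosome 2, 9948740 to 9963633, and chromosome 5, 5822841 to 5829775.

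In pkl seedlings, most tested genes of the salicylic acid defence pathway fell. The pathogenesis-related gene PR1 fell from 47.5 to 3.50 FPKM, the transcription factor gene WRKY70 from 66.8 to 10.2, ALD1, needed for systemic resistance, from 2.50 to 0.388, and SARD1, an activator of salicylic acid synthesis, from 7.79 to 2.17. Of 12 tested salicylic acid and defence genes 9 fell and 0 rose, with the same 9 and 0 adjusted over the list alone (Fisher's exact test, adjusted p = 1.81e-07). The list's median log2 fold change was -0.56. Among the largest falls in pkl, ranked over called nuclear loci above 0 in both groups with at least 5 FPKM in the higher one, PRB1 went from 30.2 to 0.374 FPKM, LURP1 from 98.8 to 2.53, NIMIN1, whose product binds the salicylic acid receptor NPR1, from 8.48 to 0.348 and PCC1 from 107 to 5.06. The sugar transporter gene SWEET10 fell from 9.29 to 0.327 and the SPIRAL1-like gene SP1L5 from 5.06 to 0.250.

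Several regulators of flowering fell in pkl. FLC, a MADS-box repressor of flowering, fell from 3.77 to 0.524 FPKM, the AP2-type repressor gene SNZ from 2.04 to 0.301 and FD, the bZIP partner of FT, from 9.15 to 2.58, while MAF4, of the FLC clade, rose from 3.52 to 10. Of 22 tested flowering time genes 2 rose and 5 fell, or 2 and 6 adjusted over the list alone (Fisher's exact test, adjusted p = 0.189 for lower members), with a median log2 fold change of -0.35, at percentile 0.01 of the random lists. Among floral organ identity genes, SEP3 fell from 9.93 to 5.77 FPKM and FUL from 1.29 to 0.372, and none of the 9 tested was called higher; adjusted over the list alone, 1 was higher and 2 were lower. The meristem gene STM fell from 7.44 to 2.47, the single call among 9 meristem and KNOX genes by either adjustment.

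Some genes of roots and of jasmonate response rose in pkl, though neither list passed its test. RSL4, a regulator of root hair growth, rose from 2.43 to 7.58 FPKM, the root hair expansin gene EXPA7 from 22.3 to 50.1, PRP3 from 129.8 to 240.1 and the root stem cell gene PLT1 from 1.04 to 1.86. These were the 4 of 12 tested root markers that rose, none fell, and 5 were higher adjusted over the list alone (Fisher's exact test, adjusted p = 0.110). The lipoxygenase gene LOX2 rose from 29.6 to 172 FPKM and PDF1.2b from 21.6 to 73.8, while VSP1 fell from 11.6 to 6.86 and VSP2 from 22.1 to 14.7. Of 7 jasmonate genes 3 rose and 2 fell, or 4 and 2 adjusted over the list alone (Fisher's exact test, adjusted p = 0.110 for higher members); with members in shared loci counted the adjusted p by the same exact test was 0.0261.

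Among Polycomb genes in pkl, RING1B, for a core subunit of PRC1, rose from 5.88 to 20.1 FPKM. ULT1 rose from 13.4 to 19.2 and SWN, for a relative of CLF, rose as well, and the demethylase gene JMJ30 fell from 124 to 94.3; of 23 tested Polycomb and related genes 3 rose and 1 fell, the same adjusted over the list alone. Most seed genes were near the floor. Of 5 tested seed maturation regulators EEL fell from 2.35 to 0.748 and none rose, with 2 lower adjusted over the list alone. Of 3 tested seed storage genes none was called; SESA4, a storage albumin gene, stood at 0.280 in wild type and 1.56 FPKM in pkl, with q = 0.0734 in the authors' deposited table, and was the 1 member higher adjusted over the list alone. The median of that list was -0.09. Over members with at least 1 FPKM it was 0.36, which rests on SESA4 and OLEO4 alone. OLEO4 stood lower in pkl, at 2.09 FPKM against 2.76 in wild type, and was not called either.

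Gibberellin genes in pkl had 3 rises and 4 falls among 17 tested, the same adjusted over the list alone, with GA3OX2 going from 1.24 to 2.62 FPKM and GA2OX8 from 3.57 to 1.89. The dehydrin gene RAB18 (AT5G66400) fell from 11 to 2.19 and COR15A rose from 3.41 to 7.99; 1 cold and abscisic acid gene rose and 2 fell of 6 tested, or 1 and 3 adjusted over the list alone. The stomatal lineage regulators SPCH and FAMA fell, from 6.05 to 3.83 and from 15.5 to 11.1 FPKM, making 2 of 6 tested and 3 adjusted over the list alone. The clock gene PRR7 fell from 4.36 to 1.63 and LHY rose from 1.09 to 2.66, with 1 higher and 2 lower of 10 tested, or 2 and 4 adjusted over the list alone. CYP79F1 and BCAT4 were the 2 of 7 glucosinolate genes that rose, 5 being higher and 1 lower adjusted over the list alone. YUC2 was the 1 auxin gene of 11 and LHCA1 the 1 photosynthesis gene of 17 that fell, the same adjusted over the list alone, and none of 9 leaf polarity, 2 cell cycle, 3 heat shock and 8 reference genes was called by either adjustment.

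Over the same loci as ranked for the falls, AT3G01345, annotated as an uncharacterized protein, had the largest rise in pkl, from 0.118 to 89.8 FPKM, a log2 fold change of 9.57. The MIR157c precursor rose from 1.88 to 145 FPKM, the metallothionein gene MT1B from 6.82 to 246, AT1G11070 from 0.245 to 7.0 and the cinnamyl alcohol dehydrogenase homolog CAD2 from 0.281 to 7.10. A locus shared by AT1G61275, AT1G61280 and AT1G61290 rose from 2.57 to 61.7, so its gene is uncertain. Over all named loci, 2608 of 19365 tested were called in pkl, 1300 higher and 1308 lower, of which 382 and 439 changed at least 2-fold.

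In clf seedlings most floral organ identity genes rose. AG, the organ identity gene of stamens and carpels, rose from 0.594 to 31.1 FPKM, AP3, of petals and stamens, from 0.225 to 7.62, the carpel gene SHP2 from 0.637 to 16.9, AP1 from 0.188 to 4.15 and SEP3 from 9.93 to 166. Of 14 tested, 12 rose and none fell, the same 12 adjusted over the list alone (Fisher's exact test, adjusted p = 5.76e-11), with a median log2 fold change of 1.71. The 6 anther and pollen markers were near 0 in every genotype, at most 0.0319 FPKM in clf and lhp1, and none was tested.

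**Figure D1:**
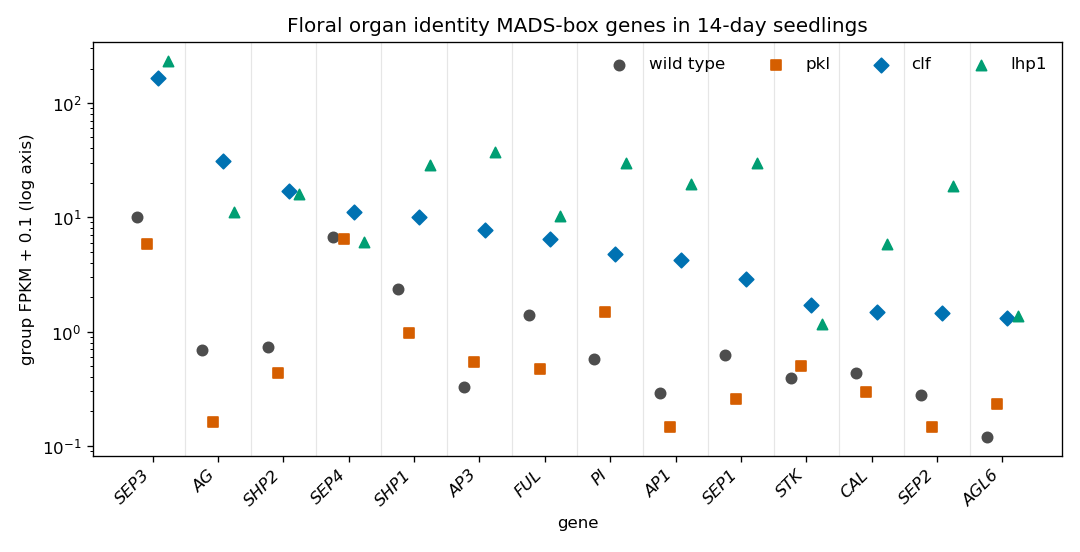
Group FPKM plus 0.1 on a log axis for the 14 floral organ identity MADS-box genes, 1 symbol per genotype as deposited by the authors, with no error bars because the tables hold 1 value per group. SEP3 stands at 9.93 FPKM in wild type, 166 in clf and 232 in lhp1, and AG at 0.594, 31.1 and 11.

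More flowering time and meristem genes rose than fell in clf. FT, the mobile flowering signal, rose from 6.17 to 37.1 FPKM, FLC from 3.77 to 16.3 and SPL3 from 6.81 to 25.3, and SNZ fell from 2.04 to 0.350. Of 22 flowering time genes 9 rose and 4 fell, or 10 and 4 adjusted over the list alone (Fisher's exact test, adjusted p = 0.000116 for higher members). The KNOX genes KNAT2, STM and KNAT1 rose, from 0.956 to 2.67, from 7.44 to 16.3 and from 8.94 to 16.6 FPKM, and the boundary gene CUC2 from 0.555 to 1.43. In all, 5 of 9 tested meristem and KNOX genes rose, or 6 adjusted over the list alone, and none fell (Fisher's exact test, adjusted p = 0.00131).

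Hormone and defence groups moved as well in clf. The storage protein genes VSP1 and VSP2, markers of jasmonate response, rose from 11.6 to 174 and from 22.1 to 146 FPKM, LOX2 from 29.6 to 74.3 and the regulator gene MYC2 from 16.5 to 32.4; 6 of 7 rose, with 6 higher and 1 lower adjusted over the list alone (Fisher's exact test, adjusted p = 1.33e-05). PDF1.2, in a locus shared with PDF1.2c and left out of these counts, fell from 38.5 to 11 FPKM. GA2OX2, for a gibberellin-inactivating enzyme, rose from 3.51 to 18.6 and the DELLA genes RGL1 from 6.64 to 21.2 and RGL2 from 1.79 to 4.22, while GA2OX8 fell from 3.57 to 0.850; 5 of 17 rose and 1 fell, the same adjusted over the list alone (Fisher's exact test, adjusted p = 0.0309), though the list's median was -0.05. CYP79F1, of aliphatic glucosinolate synthesis, rose from 17.1 to 46.1 and its neighbour CYP79F2 fell from 22.6 to 16.9; 3 of 7 rose and 1 fell, the same adjusted over the list alone (Fisher's exact test, adjusted p = 0.0439). Of 12 salicylic acid and defence genes 4 fell and 2 rose, or 5 and 2 adjusted over the list alone (Fisher's exact test, adjusted p = 0.0358 for lower members), ALD1 falling from 2.50 to 0.307 and PAD3 from 22.2 to 6.98. Some root markers fell, with the nitrate transporter gene NRT2.1 going from 1.75 to 0.545, PLT2 from 0.861 to 0.423 and CASP1 from 47.7 to 31.1; 5 of 12 fell and 0 rose, or 6 and 0 adjusted over the list alone (Fisher's exact test, adjusted p = 0.00654).

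In clf MEA, a Polycomb methyltransferase gene of the seed, rose from 0.0855 to 1.01 FPKM, the 1 call among 24 Polycomb genes by either adjustment. ABI5 rose from 2.86 to 12.2, 1 of 5 seed maturation regulators, or 2 adjusted over the list alone, and none of 2 seed storage genes was called. The leaf margin gene WOX1 fell from 4.66 to 1.57, with 2 of 10 leaf polarity genes higher and 1 lower, or 3 and 1 adjusted over the list alone. IAA29 fell from 1.7 to 0.233, with 1 auxin gene higher and 3 lower of 11, the same adjusted over the list alone. RAB18 rose from 11 to 24.0, 1 of 2 rises among 8 cold and abscisic acid genes, or 3 adjusted over the list alone. Photosynthesis genes had 1 rise and 2 falls of 17, and clock genes 1 and 1 of 10, the same adjusted over the list alone. None of 6 stomatal, 3 heat shock and 8 reference genes was called by either adjustment, and of 2 cell cycle genes none was called but 1 was higher adjusted over the list alone.

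Ranked over called nuclear loci above 0 in both groups with at least 5 FPKM in the higher one, the largest rises in clf were those of AT5G22430, of the pollen Ole e 1 family, from 0.272 to 16.5 FPKM, the B3 factor gene AT5G60140 from 0.157 to 8.38, AG, the cystatin-like gene AT1G03710 from 0.266 to 12.8, the branching regulator BRC1 from 0.127 to 5.62 and SCPL43 from 0.186 to 8.04. The largest falls over the same loci were those of AT3G16670, also of the Ole e 1 family, from 584 to 23.4, AT1G43590 from 14.5 to 0.748, the defensin-like gene AT3G05730 from 844 to 58.1, the glutaredoxin gene AT2G47880 from 62.6 to 8.70, MSRB6 from 11.6 to 1.68 and AT5G24640 from 5.16 to 0.804. AT1G43590 stood low in pkl (0.264) and lhp1 (0.268) as well, where it was not called, so its low value was not particular to clf. In clf 2406 of 19370 tested loci were called, 1384 higher and 1022 lower. At least 8-fold changes were 71 rises and 9 falls.

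Most floral organ identity genes rose in lhp1 seedlings as well. AP3 rose from 0.225 to 37.1 FPKM, AP1 from 0.188 to 19.3, PI from 0.479 to 29.6 and SEP1 from 0.522 to 30.0, and SEP3 reached 232 and AG 11. Of 14 tested, 11 rose and none fell, the same 11 adjusted over the list alone (Fisher's exact test, adjusted p = 3.41e-07), with a median log2 fold change of 3.28. Whether single members differed between clf and lhp1 was not tested. FT rose from 6.17 to 56.7 FPKM, AGL17 from 0.603 to 4.93 and TFL1 from 2.28 to 14.4, while FD fell from 9.15 to 2.09. Of 22 flowering time genes 6 rose and 7 fell, or 7 and 8 adjusted over the list alone (Fisher's exact test, adjusted p = 0.0495 for lower members, and 0.0614 with members in shared loci counted). KNAT2, STM, KNAT6 and KNAT1 were the 4 of 9 meristem and KNOX genes that rose, also adjusted over the list alone, KNAT2 going from 0.956 to 4.38 (Fisher's exact test, adjusted p = 0.0819, and 0.0276 over members with at least 1 FPKM).

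Most tested defence genes fell and most tested jasmonate genes rose in lhp1. ALD1 fell from 2.50 to 0.184 FPKM, SARD1 from 7.79 to 2.30, WRKY70 from 66.8 to 23.0 and PR5 from 38.4 to 14.3; 8 of 12 salicylic acid and defence genes fell, or 9 adjusted over the list alone, and 0 rose (Fisher's exact test, adjusted p = 0.000135). VSP1 rose from 11.6 to 106, VSP2 from 22.1 to 148, LOX2 from 29.6 to 93.8 and MYC2 from 16.5 to 26.2, 5 of 7 jasmonate genes by either adjustment (Fisher's exact test, adjusted p = 0.00427). PDF1.2, again in its shared locus and outside these counts, fell from 38.5 to 14.3. CYP79F1 rose from 17.1 to 30.9 and BCAT4 from 100.4 to 131, with 4 of 7 glucosinolate genes higher, or 5 adjusted over the list alone (Fisher's exact test, adjusted p = 0.0368). Photosynthesis genes fell on balance: PSAD-1, of photosystem I, went from 1072 to 705 and LHCA1 from 581 to 385, while LHCB2.1 and LHCB2.2 rose, from 19.1 to 31.1 and from 15.3 to 25.4. Of 17 tested 8 fell and 3 rose, or 10 and 3 adjusted over the list alone (Fisher's exact test, adjusted p = 0.00201 for lower members).

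**Figure D2:**
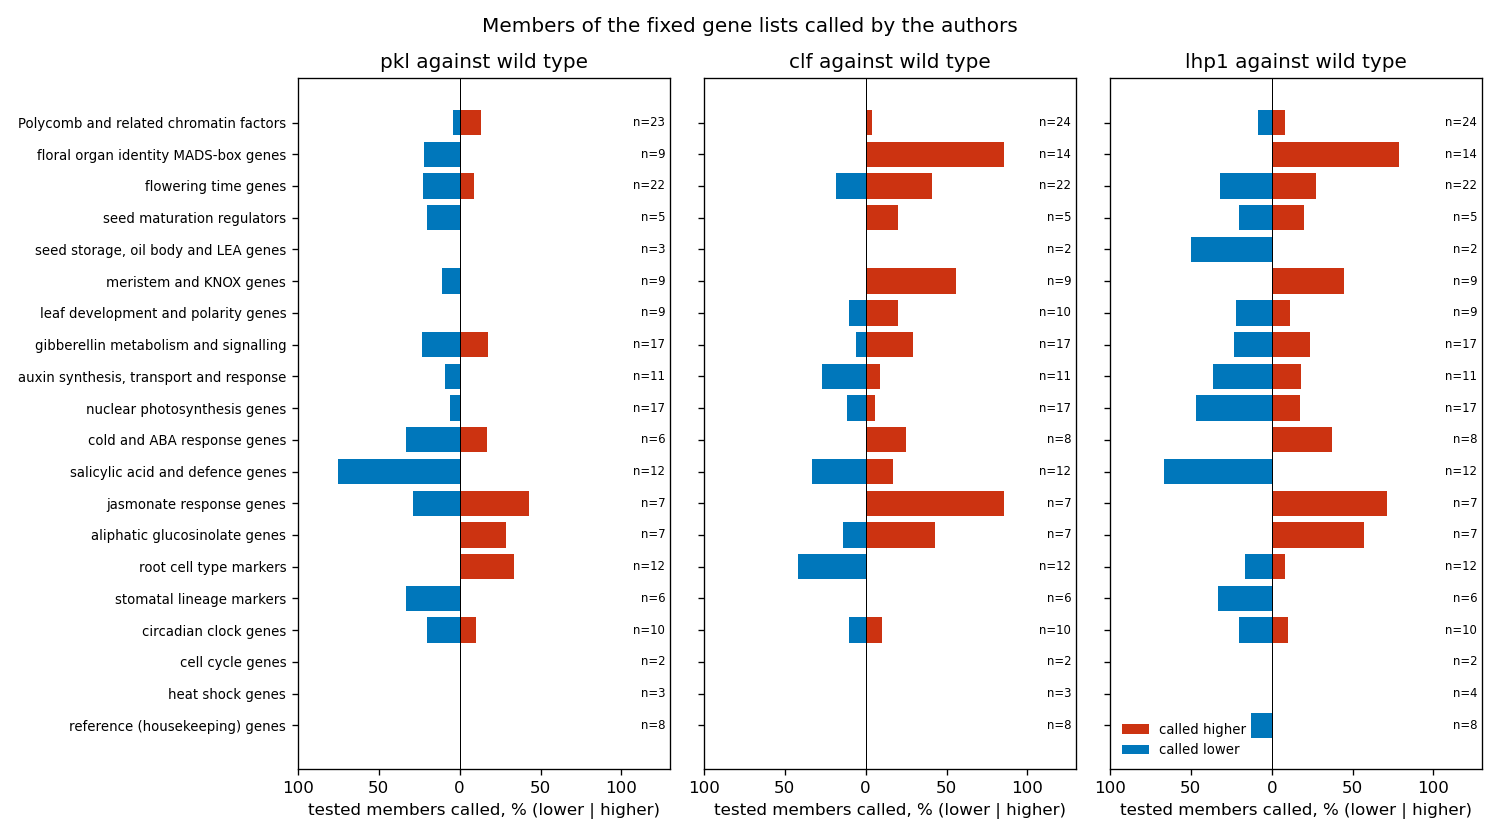
Share of tested members called higher (red, right of 0) and lower (blue, left of 0) for each fixed gene list and mutant, in percent, with the number tested at the right edge; the mutated genes and the anther and pollen markers are not drawn. Floral organ identity genes have 12 of 14 members higher in clf and 11 of 14 in lhp1, and salicylic acid and defence genes 9 of 12 lower in pkl.

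Among Polycomb genes in lhp1, MEA rose from 0.0855 to 1.05 FPKM and EMF1 from 8.91 to 12.9, while ULT1 fell from 13.4 to 7.67 and JMJ30 from 124 to 81.5, the 4 calls among 24 tested by either adjustment. Gibberellin genes had 4 rises and 4 falls of 17, or 6 and 5 adjusted over the list alone, with GA2OX8 going from 3.57 to 0.635 and RGL2 from 1.79 to 7.57. IAA29 fell from 1.7 to 0.140 and YUC9 rose from 1.14 to 3.90, with 2 auxin genes higher and 4 lower of 11, the same adjusted over the list alone. WOX1 fell from 4.66 to 0.541, with 1 leaf polarity gene higher and 2 lower of 9, and PYK10, an abundant root glucosidase gene, rose from 1916 to 3479, with 1 root marker higher and 2 lower of 12, both the same adjusted over the list alone. EPF2 fell from 7.91 to 2.50 and SPCH from 6.05 to 2.46, 2 of 6 stomatal genes by either adjustment. COR15A rose from 3.41 to 6.01, 1 of 3 rises among 8 cold genes, or 4 adjusted over the list alone. LHY rose from 1.09 to 2.13, with 1 clock gene higher and 2 lower of 10, or 3 and 3 adjusted over the list alone. ABI5 rose from 2.86 to 6.17 and EEL fell from 2.35 to 0.937 among 5 seed maturation genes, and OLEO4 fell from 2.76 to 1.33 among 2 seed storage genes, the same adjusted over the list alone. None of 4 heat shock genes was called by either adjustment; of 2 cell cycle genes none was called but 2 were higher adjusted over the list alone, and of 8 reference genes ACT2 fell, from 664 to 505.

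Over called nuclear loci above 0 in both groups with at least 5 FPKM in the higher one, the largest rises in lhp1 were those of AT5G22430, to 60.9 FPKM, the lipid transfer protein gene LTP4, from 1.17 to 228, AP3, a locus shared by DELTA-VPE and AT3G20220, from 0.146 to 18.5, AP1, and SVL3, from 0.0844 to 7.40. Among the same loci AT3G16670 fell furthest, from 584 to 7.81, followed by PRB1, from 30.2 to 0.659, AT5G57760, from 59.7 to 1.78, the galactinol synthase gene GolS2, from 5.20 to 0.217, the glucanase gene BG3, from 8.93 to 0.389, and the lectin gene AT5G03350, from 41.8 to 1.87. In lhp1 4236 of 19509 tested loci were called, 2166 higher and 2070 lower, the highest count of the 3 mutants.

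The clf and lhp1 mutants changed many of the same genes. Of 1366 loci higher in clf and 2106 higher in lhp1, among 19249 tested in both, 879 were higher in both, where independent lists would share 149 and unchanged mutants against the same wild type 7.78. Lower in both were 696, against 109.9 and 7.15. Calls in opposite directions were 28 higher in clf and lower in lhp1 and 47 the other way. Independent lists would give 147 and 112, and unchanged mutants against the same wild type gave 0 of each in simulation. A shared wild type alone lowers opposite calls, so their small number shows no shared change by itself. The log2 fold changes had a Pearson's r of 0.677 and a Spearman's rho of 0.558 across 18423 loci, which are not independent replicates. Unchanged mutants sharing a wild type would have an r of 0.502 in simulation, so a positive r alone shows no shared change. That simulated r is built in, because wild type and mutant were given equal shares of the noise. Their covariance was 0.148, beside 0.0176 simulated from the shared wild type alone with pooled noise. The simulated value was 0.353 with each locus's own noise, more than the total spread of these fold changes allows. The observed value exceeds that of the pooled noise, which was chosen after the first result was seen and was not checked otherwise.

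The pkl mutant shared more genes in like directions with lhp1 and with clf than independent lists would, and more in opposite directions with clf. With lhp1 it shared 437 higher loci (134 for independent lists, 6.85 simulated) and 609 lower loci (141 and 7.09), with 117 loci higher in pkl and lower in lhp1 (135 for independent lists) and 150 lower in pkl and higher in lhp1 (140.2). Its r was 0.329 (0.498 simulated for unchanged mutants) and its rho 0.313. The covariance was 0.0708, beside 0.0176 simulated with pooled noise and 0.329 with own noise. With clf it shared 238 higher loci (85.5 and 7.85) and 332 lower loci (70.0 and 7.85). In opposite directions, 130 loci were higher in pkl and lower in clf (66.6 for independent lists) and 184 lower in pkl and higher in clf (89.9). Across 18302 loci r was 0.178 (0.502 simulated) and rho 0.145. The covariance for pkl and clf was 0.0273, beside 0.0176 simulated with pooled noise and 0.331 with own noise. The own noise is too large in both pairs. Changes in 1 mutant alone lower an observed r, so values below the built-in simulated r do not show less sharing. Unchanged mutants gave 0 opposite calls in simulation for both pairs. Part of each excess in like directions may come from the shared wild-type libraries, which could not be split. The number for independent lists also takes every tested locus as equally likely to be called. The implied standard error was smaller at higher expression, so part of an excess in either direction, in any of these overlaps, may come from that.

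**Figure D3:**
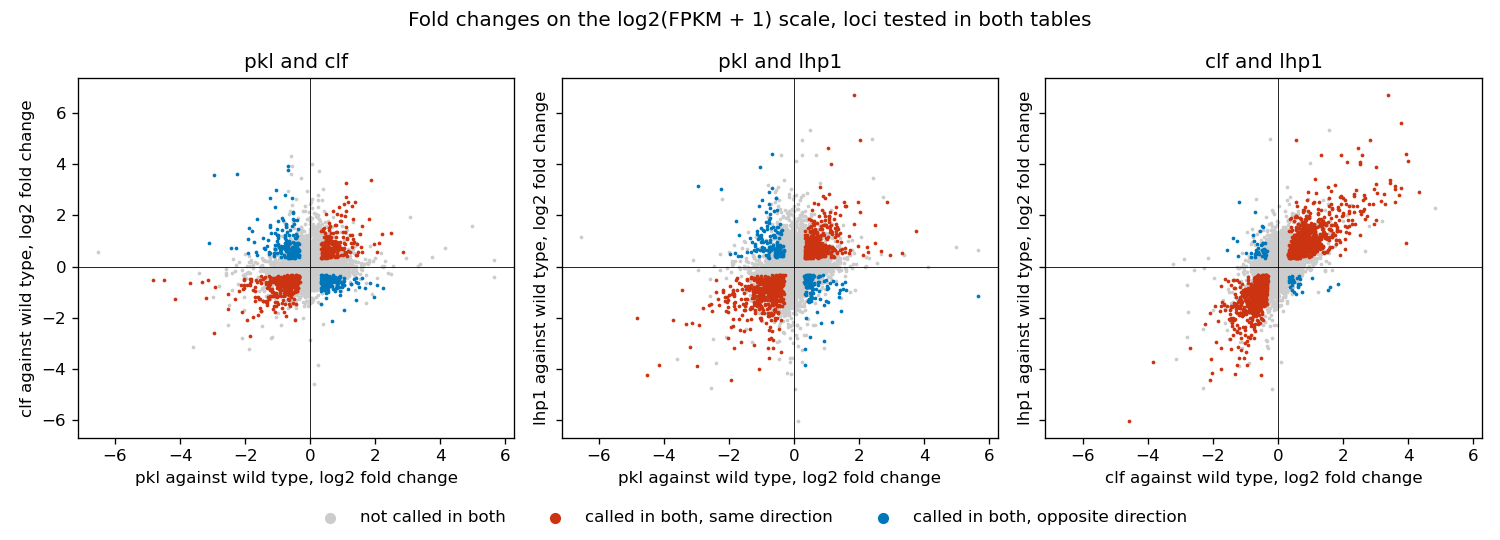
Log2 fold changes against wild type on the log2(FPKM + 1) scale for each pair of mutants, 1 point per locus tested in both with at least 1 FPKM in 1 of the groups; loci called in both are red where the direction is the same and blue where it is opposite. The correlation is 0.178 for pkl and clf, 0.329 for pkl and lhp1 and 0.677 for clf and lhp1. Unchanged mutants sharing a wild type gave 0.502, 0.498 and 0.502 in simulation, values set by its equal split of the noise.

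In all 3 mutants, 187 loci were higher, where independent lists would share 9.09 and simulated unchanged mutants 1.85, and 274 were lower, against 7.61 and 1.7. The higher set was led by LTP4, at 6.86 FPKM in pkl, 21.6 in clf and 228 in lhp1 against 1.17 in wild type. A locus shared by AT1G63055 and AT1G63057, the C2H2 zinc finger gene AT3G46080, the HSP20-like gene AT5G47600 and the peroxidase gene AT2G41480 followed, AT2G41480 going from 2.18 to 5.83, 8.39 and 12.9. The lower set was led by AT5G24640, from 5.16 to 0.448, 0.804 and 0.856, then AT5G57760, AT2G47880, the MYB-like gene RL5, from 10.8 to 3.01, 2.81 and 2.67, and a locus shared by RLP18 and AT2G15042.

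Some genes were called in opposite directions in pkl and in another mutant. SWEET10, at 9.29 FPKM in wild type, fell to 0.327 in pkl and rose to 123 in clf. The beta-amylase gene BAM5, at 7.88, fell to 0.870 in pkl and rose to 107 in clf. Both rose in lhp1 as well, SWEET10 to 89.6 and BAM5 to 72.4. SEP3 fell to 5.77 in pkl and rose to 232 in lhp1 and 166 in clf. The methyltransferase family gene AT5G37990, at 18.8, fell to 1.29 in pkl and rose to 36.6 in clf, and was not called in lhp1. The pseudogene SADHU3-2, at 5.70, rose to 14.0 in pkl and fell to 0.475 in lhp1 and 2.61 in clf.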

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

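The tests of the floral genes and of the CLF transcript were chosen after the result was seen, as was the look at loci without a gene name; the 3 tests of neighbouring loci were written before their results.

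Genes called in opposite directions in 2 mutants differed most between them as follows. The log2 ratio of pkl to clf was -8.56 for SWEET10, -6.94 for BAM5 and -4.83 for AT5G37990, and the log2 ratio of pkl to lhp1 was -5.33 for SEP3 and 4.88 for SADHU3-2. A direct test between mutants was approximate, with standard errors read back from the authors' tests (0.308 for SWEET10 and 0.184 for SEP3). The 653 opposite calls with values above 0 passed it, which adds little, because the calls had picked them; those listed at 0 in a group were not tested.

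A locus without a gene name on chromosome 5, from 14588689 to 14588838, was listed at 75606.5 FPKM in clf and at 0 in wild type, pkl and lhp1, with q = 0.00368 in the authors' deposited table for clf. It lies inside AT5G05345, an uncharacterized RNA gene annotated from 14588599 to 14589635. Short loci can take extreme FPKM from few fragments, no counts were used here, and no explanation was tested.

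Floral organ identity genes were higher in clf and lhp1, which formed flowers in the sampled seedlings could also bring. The highest anther or pollen marker in either mutant stood at 0.0319 FPKM, which argues against flowers with formed anthers. More shoot meristem or young flower tissue stays open: the larger of the median rises of WUS, CLV3 and LFY was 0.274 FPKM and the highest single rise 0.722, too small for the level set for it and too large to exclude it. A loss of repression in the mutants was not told apart from that tissue by any value used here.

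The CLF transcript was far lower in clf yet past no threshold over all genes. A candidate explanation is that the authors' p-values are inflated where 1 group is near 0. Among loci with a statistic within 0.5 of that of CLF and a higher group within 4-fold of its level, p was above 0.001 for 18 of the 30 with 1 group under 0.3 FPKM (60%, Wilson 95% interval 42.3 to 75.4) and for 10 of 552 others (1.81%, 0.987 to 3.30). The smallest p of the tables was reached by 7 of the 30 and by 539 of the 552, and it lies below the 0.001 counted here. The p of CLF in the authors' deposited table was 0.0089. The loci were not matched for the size of their change. Spread between the clf libraries at CLF stays open, since q was 0.0520 and values of single libraries were not used here.

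Neighbouring loci were called in the same direction in pkl more often than in shuffled orders, 293 pairs against a mean of 176 and a highest of 224 in 1000 shuffles. A stretch of other DNA filling most of the window within 2 Mb of PKL is argued against by the odds ratio of a call there, 1.01 (95% interval 0.815 to 1.25). The test pooled both directions over the whole window, so it cannot speak to a much shorter stretch. Overlapping models are argued against as the whole cause, with 86 pairs more than 5 kb apart (highest shuffle 45). Leaving out pairs with the same annotated product left 251 (highest shuffle 216). Only identical product texts were left out, so relatives with differently worded products could remain, and families of similar genes stay open. The clf and lhp1 tables also held more such pairs than any shuffle, 254 (highest 191) and 635 (highest 525), so the pattern was not particular to pkl. The shuffles did not hold gene density or expression level fixed, and no biological explanation was tested.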

How the results depend on the processing

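Alternatives on unnamed loci, multi-gene loci, loci listed at 0 and the deposited statistic were chosen after the data had been seen. No paired analysis was possible because the tables hold 1 value per group. Leaving out replicates, the replicate block, the count models, the pseudocount and filter for replicate values, and other splits of the samples were not run for the same reason.

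A q threshold of 0.01 left 826 higher and 857 lower loci in pkl and 628 lower in clf; shared loci became 134 higher and 203 lower for pkl and clf, 258 and 404 for pkl and lhp1, and 436 lower for clf and lhp1. A 2-fold minimum left 382 higher and 439 lower in pkl, 492 and 236 in clf and 804 and 630 in lhp1; shared loci became 52 and 70 for pkl and clf, 100 and 154 for pkl and lhp1, and 311 and 155 for clf and lhp1. Both settings are stricter by construction, and the other 4 counts at 0.01 stayed within 1.5 times. The 6 counts of called loci stayed so under 1 and 5 FPKM minimums, recomputed q-values and normal p from the statistic. They also did with centring and for unnamed, multi-gene and zero loci, where little could change. Centring leaves every q as it is and can turn only the direction of very small changes. In lhp1, with the most, 31 calls lacked a name, 329 held several genes and 54 were listed at 0. Such numbers were too few to move a count 1.5 times. The 6 counts shared by a pair of mutants stayed within 1.5 times with the 1 FPKM minimum, the 1 other alternative run for them. The counts shared by all 3 mutants were not rerun.

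The correlation of pkl and clf was 0.192 with a pseudocount of 0.1, 0.155 at 5 FPKM or more and 0.145 as Spearman's rho. For pkl and lhp1 it was 0.315 at 5 FPKM or more and 0.313 as rho, and for clf and lhp1 0.702 with a pseudocount of 0.1 and 0.558 as rho. The sign shows nothing, since unchanged mutants sharing a wild type gave about 0.50 in simulation; the cause was not tested.

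Of the list tests, meristem genes higher in lhp1 passed with members of at least 1 FPKM (adjusted p = 0.0276 by Fisher's exact test). With members in multi-gene loci, flowering time genes lower in lhp1 no longer passed (0.0614) and jasmonate genes higher in pkl did (0.0261), by the same exact test; the cause was not tested. The median of seed storage genes in pkl turned from -0.09 to 0.36 over members of at least 1 FPKM, where only SESA4 and OLEO4 remain. A list median counted as moved once its shift reached a set fraction of the central range of the random-list medians, well short of the full range. By that rule other list medians moved in 15 cases with that minimum and in 19 with a pseudocount of 0.1, and 47 did not in each. Of 725 calls and values of single genes, 69 were no longer called at 0.01. Normal p from the statistic added 27 and removed 2, and recomputed q-values added 1 and removed 3. Centring, which leaves q as it is and can only turn a direction, changed 0. Depth is unknown, and small changes of weakly expressed genes were beyond these tables.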

Other observations

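Families defined by words in the annotation were chosen after the tables had been seen and before any family was tested, in 234 tests of which 46 passed after adjustment; their members overlap with the lists of the report. A family that passed held more calls in a direction than its size would give among all tested single-gene nuclear loci, of which 7.09% were higher and 7.11% lower in pkl, 7.56% and 5.55% in clf and 11.8% and 10.8% in lhp1. The exact test, here and for the lists, counts members as independent. Neighbouring loci were called together more often than in any shuffle, so its p-values may overstate the evidence where members lie side by side. Of 68 tested homeobox genes, 23 were higher and 4 lower in clf (Fisher's exact test, adjusted p = 4.54e-08 for higher). In lhp1, 21 were higher and 14 lower (by the same exact test, adjusted p = 0.000319 for higher and 0.0569 for lower). HB21 (AT2G18550) went from 0.704 FPKM in wild type to 19.7 in clf and 8.70 in lhp1, and ATHB54 from 1.3 to 35.7 and 39.3. Of 50 NAC domain genes, 10 were higher and 3 lower in clf, and 13 were higher and 6 lower in lhp1, where the higher side passed in both, NAC2 (AT3G15510) going from 5.04 to 22.2 and 40.2. Of 61 SAUR-like genes, of auxin-driven growth, 12 were lower and 3 higher in clf, and 16 were lower and 6 higher in lhp1, where the lower side passed in both, SAUR63 going from 7.52 to 2.50 and 1.47.

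Of 19 cysteine-rich receptor-like kinase genes, 8 were lower and 1 higher in pkl, 7 and 0 in clf and 12 and 1 in lhp1 (Fisher's exact test, adjusted p = 0.000328, 0.000576 and 2.83e-06 for lower), CRK4 going from 7.38 FPKM to 1.82, 2.46 and 2.04. Of 115 disease resistance genes with TIR or NB-ARC domains, 21 were lower and 5 higher in pkl, where the lower side passed (adjusted p = 0.000678 by the same exact test); it did not pass in clf or lhp1. In pkl, 22 of 108 pectin lyase and methylesterase genes rose and 13 fell, where the higher side alone passed (Fisher's exact test, adjusted p = 0.000122). In clf the lower side alone passed, with 17 of 108 lower and 9 higher (adjusted p = 0.00106 by the same exact test), and in lhp1 neither did. Peroxidase genes passed in both directions in pkl, 14 of 52 higher and 10 lower. For these the lower side alone passed in clf, 13 of 52 against 7 higher, and the higher side alone in lhp1, 23 of 53 against 6 lower. Of 104 loci annotated as pseudogenes in pkl, 18 were higher and 6 lower (Fisher's exact test, adjusted p = 0.00304 for higher). The higher ones included the retroelements SADHU5-1, from 7.87 to 20.8, and Sadhu4-2, from 30.9 to 51.7. Of 100 loci in the separate class of transcribed pseudogenes, 8 were higher and 5 lower in pkl, near the shares of all loci, and neither side passed. In lhp1 the lipid transfer protein genes went both ways, 23 of 63 higher and 16 lower, LTP3 rising from 5.0 to 150.5 and AT4G22517 falling from 323 to 49.1.

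Some large differences passed no threshold. Of loci changed at least 8-fold with 5 FPKM or more in the higher group, 9 of 46 were not called in pkl, 12 of 52 in clf and 20 of 112 in lhp1.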
